A study of Mus musculus with 6 samples.

How the data were processed

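Per the labels' protocols, total RNA was extracted from mouse bone marrow-derived mesenchymal stem cells carrying a scrambled or an anti-miR-30e oligo, copied with an oligo(dT)-T7 primer, transcribed into biotin-labelled cRNA and run on Affymetrix arrays. The sample titles gave the 3 arrays of each group and their replicate numbers. The series describes 3 experiments, of which the transfected stem cells are analysed here and the lentivirus experiments are not used here.

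The deposited table holds log values, taken as log2, with 28856 probe sets on 6 arrays. Each row has a median of 0 over the arrays (largest absolute row median 5e-07), so the authors' values are centred on each probe set and hold no level. The summarization, background correction, normalization between arrays, log base and direction are not given in the sources used here. A base other than 2 would rescale every log2 value and fold, and the opposite direction would turn every sign; neither could be tested on these values. Centring on the row median cancels in a difference between groups. No separate background or signal level was at hand. Precision is given by the spread over the 3 arrays per group, which the gene test below moderates with the variances of other genes.

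Probe sets were named through the platform annotation. It gave 1 symbol for 21789, several for 1621 and no gene for 5446 probe sets, the last being unnamed here. Of the 21789, 21698 matched the mouse reference table (assembly GRCm38.p6) by gene ID and took its symbol. That table was used for names and the genomic span of genes, and no coordinates are printed because the build of the platform annotation is not given in the sources used here. Probe sets with several genes were left out of the gene tests. The values of probe sets of 1 gene were averaged, giving 19938 genes, of which 18939 had 1 probe set and 999 had more.

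Genes were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes, anti-miR-30e minus scrambled, on all 6 arrays, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Every adjusted p of a gene is from that test, and errors of log2 differences are its moderated standard errors. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 24 lists, with lists under 5 measured genes given no test. Camera with an estimated correlation and fry were run beside it. The 24 lists held 456 entries, of which 420 were measured. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

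The lists, tests, alternatives and naming rule were chosen before the data were examined. The rule named the 12 genes with the largest rise and the 12 with the largest fall among changed genes whose groups did not overlap, 6 genes always, of which 3 were measured (Igf2, Alpl and Nfyc) and the others were not analysed here, and up to 4 members of each list with the smallest p. Near-identical family members are given as uncertain. Genes named outside this rule (Dnm1l, Mtdh, Col1a1, Lss, the miR-30 precursors, and the annexin, Hox, histone demethylase and ribosomal protein genes) were chosen after their values were seen.

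The form of the table forced departures from the chosen design. A filter on dim genes and the choice of the probe set with the highest mean need levels, so no filter and the mean of a gene's probe sets became the main setting, both of them alternatives chosen with the design. The planned trend of variance on mean level was replaced by eBayes without a trend, another such alternative, because the mean of centred values is not a level. These replacements were made from the structure of the table before any test was run. The planned test of genes with miR-30 seed sites needs 3' UTR sequences and was not analysed here, so the list of reported targets stands alone.

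On simulated data for this comparison with 200 of 19938 genes changed, the test recovered 91% of changes of 0.5 and 100% of changes of 1 on the log2 scale, with 7.28% false among its calls, and it made 0 calls with no change. The simulated noise was normal, independent between genes and of equal spread on all arrays, from the variances limma fitted here. The real arrays differed in spread, genes varied together, and the median change called was 0.38, so these rates may not hold for them.

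Alternatives were quantile normalization, centring arrays on their medians, the replicate number as a block, array weights, leaving out each array in turn, eBayes with a trend and with a robust trend, all probe sets, and a statistic with each gene's own variance. Added after seeing the data were leaving out 1234 olfactory, vomeronasal and taste receptor genes, genes with 1 probe set alone, leaving out both replicate 2 arrays, camera with the correlation fixed at its estimate for each list (0 where negative), and removing from each array a lowess trend (span 0.3) on the log genomic span of genes. Gene families, taken as 237 groups of at least 10 genes sharing a symbol stem, were examined after the lists. The set of 54 ribosomal protein genes was formed after the families were seen, and was narrowed once, after its values were seen, to leave out ribosomal protein-like paralogues.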

Results

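Mesenchymal stem cells (MSCs), bone marrow stromal cells that can form bone, fat and cartilage, had been isolated from C57BL/6 mice and transfected with 1 of 2 oligonucleotides. The control was a scrambled oligo, and the other was an anti-miR-30e oligo, an antisense oligo of the kind used to block a microRNA. Total RNA of 3 samples per group was measured on 6 Affymetrix arrays, and 28856 probe sets gave values for 19938 named genes. The deposited values are relative to each probe set's own median over the 6 arrays, so they show differences between arrays and no expression level. The log base and the direction are not given in the sources used here. Base 2, with positive values as higher expression, was assumed for every value and fold below. Array medians ran from -0.00346 in scrambled replicate 1 to 0.0137 in scrambled replicate 2. The SD over probe sets was widest on the replicate 2 array of both groups, at 0.147 for the scrambled and 0.132 for the anti-miR-30e array, against 0.0951 to 0.109 on the other arrays. The number of arrays limits the precision. Nothing in the labels says that the 3 samples of a group came from separate cultures or animals. The p-values therefore rest only on the spread between these samples, which may be technical. In the gene test each gene's variance is also drawn towards that of other genes (5.72 prior degrees of freedom).

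The comparison asked which transcripts differed between MSCs given the anti-miR-30e oligo and MSCs given the scrambled oligo. Id2, an inhibitor of basic helix-loop-helix transcription factors, rose 2.62-fold with the anti-miR-30e oligo (1.39 ± 0.12 on the log2 scale, SE, n = 3 per group, adjusted p = 0.00102). Ndnf, which encodes a secreted neurotrophic factor, rose 2.13-fold (1.09 ± 0.11), and the kinesin motor gene Kif1a rose 2.11-fold (1.08 ± 0.08). Omd, which encodes osteomodulin, a proteoglycan of bone matrix, rose 1.86-fold (0.90 ± 0.09). Slc40a1, which encodes the iron exporter ferroportin, fell by 1.19 ± 0.09 on the log2 scale and was 2.28-fold lower (adjusted p = 0.000482).

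Further rises among the 12 largest were those of Stard6, a lipid-binding START domain gene (1.00 ± 0.09 on the log2 scale), and Chmp2b, a subunit of the ESCRT-III membrane-scission complex (0.95 ± 0.09). Fkbp9, a peptidyl-prolyl isomerase of the endoplasmic reticulum, rose by 0.93 ± 0.06 and had the smallest adjusted p of all genes, 0.000296. Srp14, a subunit of the signal recognition particle, rose by 0.90 ± 0.10, and Pamr1 by 0.90 ± 0.07. Plagl1, an imprinted zinc-finger gene, rose by 0.80 ± 0.07, and Rbm18 by 0.77 ± 0.06. Among probe sets of 1 gene symbol, averaged by gene, the largest rise past the threshold, 1.40 ± 0.10, belonged to Prl2c5, one of several near-identical prolactin family genes, so its identity is uncertain. Group means on the relative log2 scale were -0.81 ± 0.28 with the scrambled and 0.58 ± 0.04 with the anti-miR-30e oligo for Id2 (SD, n = 3).

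Ankrd52, a regulatory subunit of protein phosphatase 6, fell by 0.93 ± 0.06 on the log2 scale. The lysosomal galactosylceramidase gene Galc fell by 0.81 ± 0.09, and Txnip, which encodes thioredoxin-interacting protein, fell by 0.81 ± 0.08. The linker histone gene H1f3 fell by 0.75 ± 0.09, the chloride-proton exchanger gene Clcn5 fell by 0.70 ± 0.07 and the kinetochore gene Zwint fell by 0.70 ± 0.06. The values of the other 5 of the 12 largest falls were -0.68 ± 0.10 for Entpd6, -0.68 ± 0.10 for Prkar2a, a regulatory subunit of protein kinase A, -0.68 ± 0.07 for the tetraspanin gene Cd151, -0.67 ± 0.07 for Avil and -0.67 ± 0.08 for Angptl4, an inhibitor of lipoprotein lipase.

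**Figure D1:**
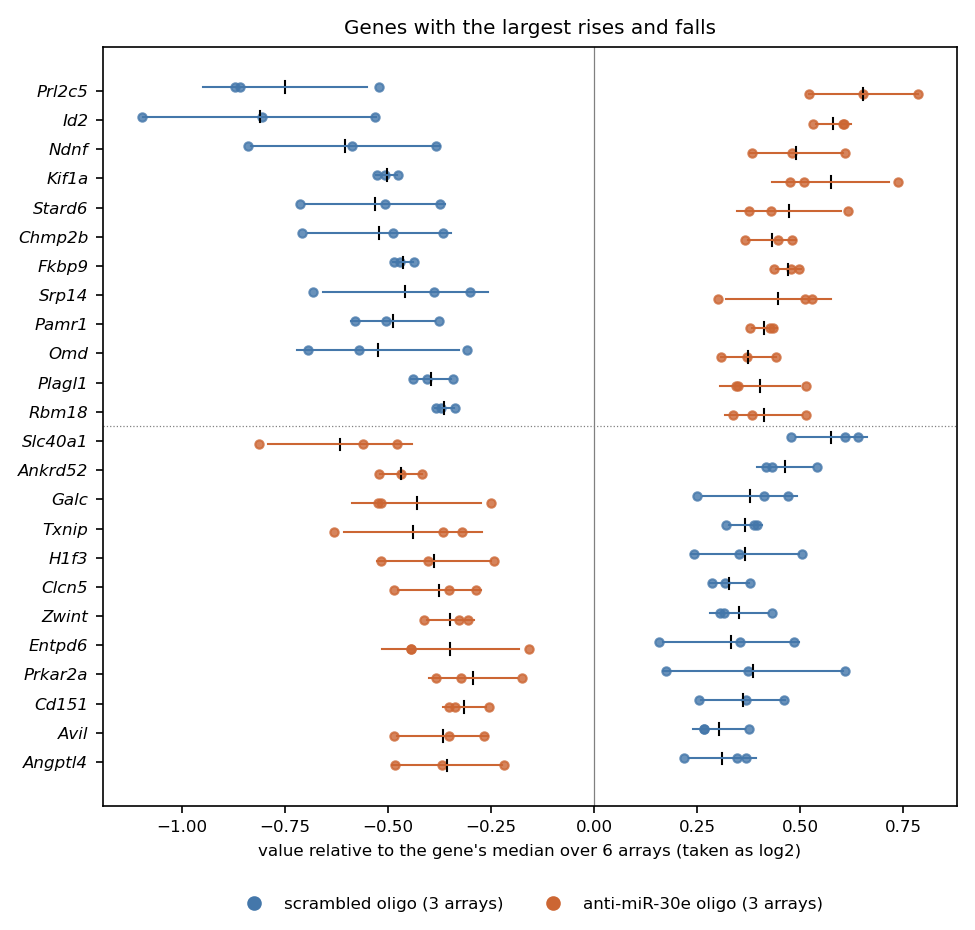
Value of each array relative to the gene's median over the 6 arrays (horizontal axis, taken as log2) for the 12 largest rises (top) and 12 largest falls (bottom) past the threshold. Points are arrays, ticks are group means and lines the SD over 3 arrays; the arrays of the groups do not overlap for any of these genes.

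In all, 584 of the 19938 genes changed at an adjusted p under 0.05, of which 266 were higher and 318 lower with the anti-miR-30e oligo. With quantile normalization between arrays the same split was 473 higher and 286 lower. The groups did not overlap for any of the 584 genes, and for 4058 of all genes (20.4%). The average over all splits of the 6 arrays 3 against 3 is 10%. Because genes vary together, 1 split can lie above it without an oligo effect, and the other splits' shares were not computed. Differences were small, with a median absolute log2 difference of 0.38 among changed genes, and 6 genes passed 2-fold. The count was 322 without scrambled replicate 1, 167 without scrambled replicate 3, 190 without anti-miR-30e replicate 1 and 143 without anti-miR-30e replicate 3. It was 138 with a replicate block, 1976 with array weights, 1255 (303 higher, 952 lower) without both replicate 2 arrays and 1 (Fkbp9) with a variance estimated for each gene alone, and without anti-miR-30e replicate 2 the higher genes numbered 143.

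Reported targets of the miR-30 family, and the family's own precursors, were examined because the oligo was directed at miR-30e. Igf2, insulin-like growth factor 2, rose 1.25-fold with the anti-miR-30e oligo (0.32 ± 0.06 on the log2 scale, SE, adjusted p = 0.0204), from -0.14 ± 0.02 with the scrambled oligo to 0.18 ± 0.06 (SD, n = 3 per group). Snai1, a repressor of epithelial genes, fell by 0.40 ± 0.06 and the glycosyltransferase gene Galnt7 fell by 0.52 ± 0.11. The probe set of the miR-30e precursor gave -0.13 ± 0.09 (95% confidence interval -0.34 to 0.07, adjusted p = 0.58), and its host gene Nfyc -0.09 ± 0.06 (adjusted p = 0.57). The 5 other measured precursors of the miR-30 family lay between -0.16 and 0.16, and none passed. The arrays do not measure mature microRNAs, so these values do not check the block.

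Of 26 measured genes reported as miR-30 targets, 1 rose, 2 fell and 23 did not pass, whereas 3 rose and 3 fell adjusted over the list alone. The added genes were Mtdh (0.26 ± 0.07) and Dnm1l (0.23 ± 0.07) on the higher side and Ddit4 (-0.31 ± 0.08) on the lower, which did not pass over all genes. The list did not stand apart from other genes (camera, adjusted p = 0.544 and 0.904 with an estimated correlation). Its median was 0.03, its mean -0.01, and the test's direction was up, so their signs differ. Camera sets a list against other genes, and the median log2 difference over all genes was -0.025. Here and below, camera's direction is therefore relative to a centre below 0. Counts of positive and negative members are likewise not to be read against an even split. Igf2 was put in this list because the study is known to concern it, so its rise is not independent evidence of the list's direction.

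In the IGF axis, Igf2 was joined by falls of 3 genes. Igfbp5, an IGF-binding protein, fell by 0.52 ± 0.09 on the log2 scale, the RNA-binding protein gene Igf2bp3 fell by 0.48 ± 0.07, and Igf1 fell by 0.38 ± 0.07 (adjusted p = 0.0193). Of 16 measured members, 1 rose, 3 fell and 12 did not pass. Adjusted over the list alone, 3 rose and 5 fell, and the list test gave an adjusted p of 0.578.

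The osteoblast, adipocyte and chondrocyte lists, for lineages that MSCs can enter, were not called. Of 20 measured osteoblast genes, Omd rose and 19 did not pass, with the same count adjusted over the list alone. Alpl, which encodes the alkaline phosphatase of mineralizing cells, was at -0.01 ± 0.08 (95% confidence interval -0.19 to 0.18), Col1a2 at -0.21 ± 0.06 and Col1a1 at -0.18 ± 0.07. The list's median was -0.02, its mean 0.02 and its test up (adjusted p = 0.704). Of 23 adipocyte genes, Lpl (lipoprotein lipase) fell by 0.40 ± 0.06, Pparg, the transcription factor that directs fat cell formation, fell by 0.32 ± 0.06, and Scd1, a fatty acid desaturase, rose by 0.31 ± 0.07. The other 20 did not pass, 3 rose and 3 fell adjusted over the list alone, and the list test gave an adjusted p of 0.578, with a median of -0.003, a mean of 0.001 and a direction of up. None of 15 chondrocyte genes changed, over all genes or adjusted over the list alone (Acan -0.14 ± 0.06, Col2a1 -0.12 ± 0.07, list adjusted p = 0.756).

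None of 15 smooth muscle contractile genes passed over all genes or adjusted over the list alone, but 13 of the 15 values were positive. Cnn1, which encodes calponin, gave 0.27 ± 0.09, Lmod1 0.21 ± 0.07 and Des, which encodes desmin, -0.25 ± 0.10. As a list they lay above other genes (adjusted p = 0.00705), with an adjusted p = 0.756 with an estimated correlation. Without scrambled replicate 2 the adjusted p was 0.0526, and without both replicate 2 arrays, whose spread was widest, it was 0.0656.

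In BMP and TGF-beta signalling, Id2 and Id1 (0.42 ± 0.07), both induced by BMPs, rose together with Grem1, a secreted BMP antagonist (0.36 ± 0.06), and Tgfbi, a matrix protein induced by TGF-beta, fell by 0.32 ± 0.05. Of 22 members 3 rose, 1 fell and 18 did not pass. The counts adjusted over the list alone were 4 and 1. The list test gave an adjusted p of 0.544 in the upward direction, with a median of -0.02 and a mean of 0.05. In Wnt signalling, the secreted modulator gene Sfrp2 (0.58 ± 0.08) and the receptor gene Fzd1 (0.40 ± 0.06) rose and 19 of 21 members did not pass. Adjusted over the list alone, 4 rose and 2 fell (list adjusted p = 0.0946, and 0.0396 without anti-miR-30e replicate 2).

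Of 24 genes of the extracellular matrix and its remodelling, the stromelysin gene Mmp3 rose (0.27 ± 0.06, adjusted p = 0.0498) and the collagen gene Col6a3 fell by 0.29 ± 0.06, while 22 did not pass. Adjusted over the list alone, 5 rose and 3 fell, and the list adjusted p was 0.388. Of 16 MSC and stromal markers, Kitl, which encodes stem cell factor, rose by 0.46 ± 0.07 and 15 did not pass, with the same count adjusted over the list alone. The list adjusted p was 0.0635, and it lay under the threshold without scrambled replicate 1 (0.0296), scrambled replicate 3 (0.0290) or anti-miR-30e replicate 3 (0.0249).

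Markers of other bone marrow cells were used to look for a difference between the groups in cells of another type. The values hold no level, so such cells at a similar share in both groups would not be seen. None of 19 macrophage and monocyte markers (Cd68 -0.25 ± 0.11, list adjusted p = 0.544), 12 neutrophil markers (Elane -0.17 ± 0.06, list adjusted p = 0.578) or 9 lymphoid markers (Ms4a1 -0.13 ± 0.06, list adjusted p = 0.776) changed, over all genes or adjusted over the list alone. Of 6 erythroid markers 0 passed over all genes and 1 fell adjusted over the list alone, the carbonic anhydrase gene Car2 (-0.24 ± 0.06, adjusted p = 0.0513 over all genes, list adjusted p = 0.342). Of 12 endothelial markers, Tek, the angiopoietin receptor gene, rose by 0.69 ± 0.08 and 11 did not pass, with the same count adjusted over the list alone. Its list gave an adjusted p of 0.578 upward with a median of -0.03 and a mean of 0.03, and 0.0402 without both replicate 2 arrays.

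The cholesterol synthesis list lay above other genes at the preset correlation (adjusted p = 2.71e-09), and was not called with an estimated correlation of 0.737 (adjusted p = 0.904) or by fry (0.250). Cyp51, the lanosterol demethylase gene, rose by 0.42 ± 0.08 on the log2 scale and the HMG-CoA synthase gene Hmgcs1 rose by 0.37 ± 0.08. Idi1 (0.55 ± 0.13) and Lss (0.42 ± 0.10) were at adjusted p = 0.0505 and 0.0513. Of 16 members, 15 had positive values, 2 rose and 14 did not pass, and 9 rose adjusted over the list alone. The mean over the list was -0.14 ± 0.12 with the scrambled and 0.08 ± 0.05 with the anti-miR-30e oligo (SD, n = 3 per group), where an exact permutation test of 3 against 3 cannot go below p = 0.1. The lowest list mean, -0.28, was that of scrambled replicate 2, an array of wide spread.

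The small RNA machinery list lay below other genes at the preset correlation (adjusted p = 0.00251), and was not called with an estimated correlation (adjusted p = 0.904) or by fry (0.211). Dicer1, the nuclease that cuts microRNA precursors, fell by 0.58 ± 0.07 on the log2 scale. Ago2, an Argonaute that carries microRNAs, fell by 0.42 ± 0.06 (adjusted p = 0.00728). The Dicer partner gene Tarbp2 fell by 0.32 ± 0.07 and the silencing scaffold gene Tnrc6b fell by 0.25 ± 0.05. Of 14 members, 11 had negative values, 4 fell, 0 rose and 10 did not pass, while 6 fell adjusted over the list alone. The members include Nfyc (-0.09 ± 0.06), which is the miR-30e host gene rather than a part of this machinery. Over genes with 1 probe set alone, a setting chosen after seeing the data, the list's adjusted p at the preset correlation was 0.0702. That setting leaves out Ago2, Tarbp2 and Nfyc, which have 2 probe sets each, so it removes falling members of the list.

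**Figure D2:**
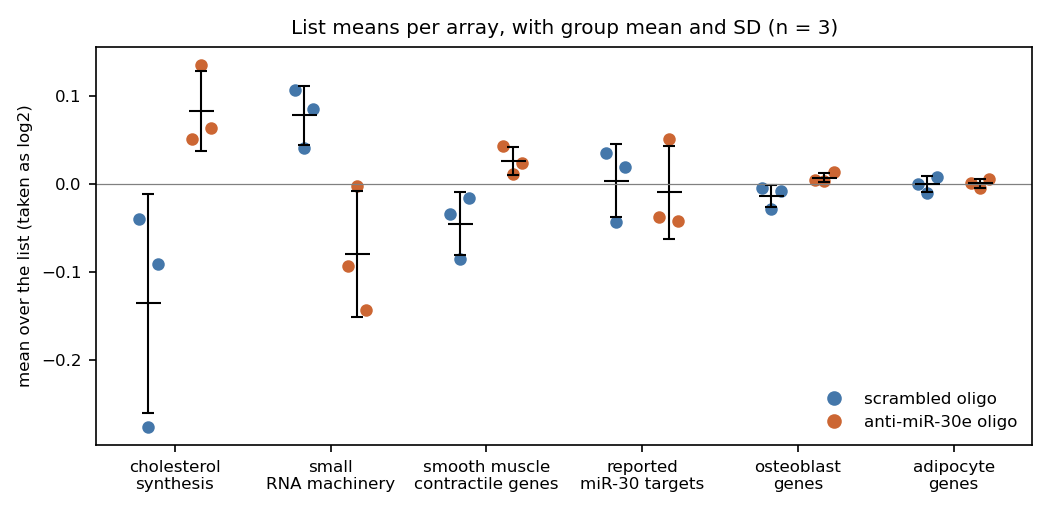
Mean over the members of 6 fixed lists on each array (vertical axis, relative values taken as log2), with points for arrays and bars for the group mean and SD (n = 3). Cholesterol synthesis means were -0.14 with the scrambled and 0.08 with the anti-miR-30e oligo, small RNA machinery means 0.08 and -0.08.

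Among interferon-induced genes, the chemokine gene Ccl5 rose by 0.58 ± 0.11 and 19 of 20 did not pass, with 2 rising and 1 falling adjusted over the list alone (Rsad2 -0.81 ± 0.21, adjusted p = 0.0735 over all genes). The list adjusted p was 0.860 upward, with a median of -0.05 and a mean of -0.03. Among 20 NF-kB inflammatory genes, Il1rn, which encodes the interleukin-1 receptor antagonist, rose by 0.57 ± 0.11, 19 did not pass, and 3 rose adjusted over the list alone (list adjusted p = 0.541). In the cell cycle list, the cyclin gene Ccne1 fell by 0.46 ± 0.07 and 24 of 25 did not pass, also adjusted over the list alone. That list's adjusted p was 0.342, and 0.00764 without scrambled replicate 1.

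In the unfolded protein and amino acid stress list, the glutathione-degrading enzyme gene Chac1 rose by 0.38 ± 0.08, the endoplasmic reticulum gene Sdf2l1 fell by 0.30 ± 0.06 and 17 of 19 did not pass. Adjusted over the list alone, 2 rose and 4 fell (list adjusted p = 0.859). None of 15 p53 target genes changed, over all genes or adjusted over the list alone (Plk2 0.21 ± 0.07, list adjusted p = 0.541, upward, with a median of -0.01 and a mean of 0.02). In the autophagy list the kinase gene Ulk1 fell by 0.30 ± 0.07 and 17 of 18 did not pass, also adjusted over the list alone (list adjusted p = 0.859, upward, with a median of -0.03 and a mean of -0.01). Of 17 hypoxia and glycolysis genes, Adm, which encodes adrenomedullin (0.41 ± 0.07), Ndrg1 (0.34 ± 0.06) and the glycolytic enzyme gene Pgk1 (0.30 ± 0.05) rose and 14 did not pass. The count of rises adjusted over the list alone was 4, and the list adjusted p was 0.541 upward, with a median of -0.06 and a mean of 0.02.

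**Figure D3:**
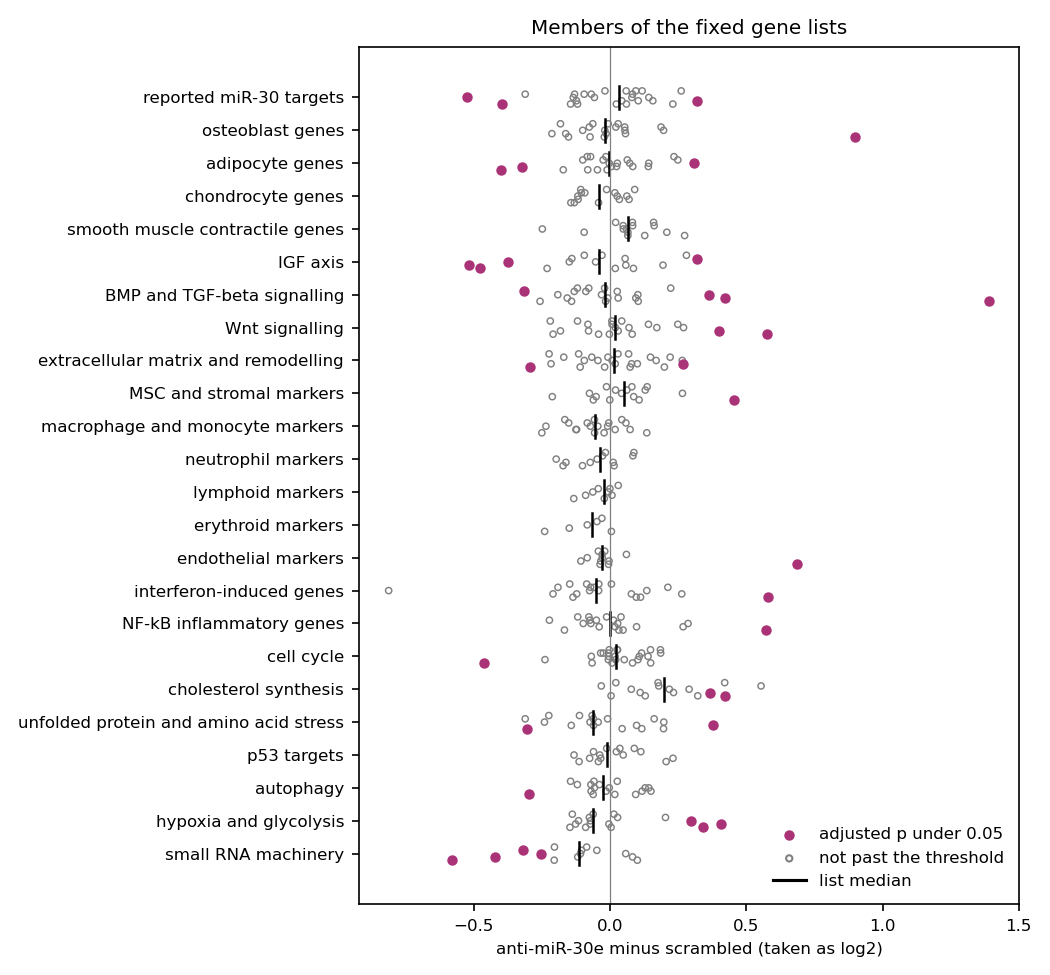
Log2 difference, anti-miR-30e minus scrambled (horizontal axis), of each measured member of the 24 fixed lists. Filled points passed an adjusted p of 0.05 over all genes, open points did not, and bars are list medians; the cholesterol synthesis median was 0.20 and the small RNA machinery median -0.11.

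Of the 24 lists, 3 were called with the preset correlation (cholesterol synthesis, small RNA machinery and smooth muscle contractile genes) and 0 with an estimated correlation. The test fry, which asks whether the members of a list move 1 way on balance, called 0, and its mixed form, which asks whether they change in either direction, called 18. Fry does not compare a list with other genes, and 2951 of all 19938 genes had an unadjusted limma p under 0.05. The 18 calls therefore do not set those lists apart from other genes.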

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

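The signals here come from probe sets outside the named genes, and no test of an explanation was run for them. Among the 5446 probe sets with no gene listed, 23 changed when all 28856 probe sets were tested with limma, 16 of them higher and 7 lower with the anti-miR-30e oligo. The smallest adjusted p-values of each direction belonged to probe sets 10345791 (0.81 ± 0.10 on the log2 scale, SE) and 10608138 (0.48 ± 0.06), which were higher, and 10523717 (-0.71 ± 0.06) and 10367335 (-0.67 ± 0.07), which were lower. A probe set listing Prl2c2, Prl2c3 and Prl2c4 rose by 1.52 ± 0.10 (adjusted p = 0.00257), and cannot be assigned to 1 of these near-identical genes. A further 7 probe sets with no gene listed differed by over 2-fold, from 1.40 to 2.16, but did not pass (adjusted p from 0.0778 to 0.245). On these 7, anti-miR-30e replicate 1 read 2.13 to 2.59 and replicate 2 read 1.06 to 1.55, whereas replicate 3 read -0.20 to 0.20, and scrambled replicate 1 also read -0.20 to 0.20. These mirror each other because each row is centred on its median, and scrambled replicates 2 and 3 read -1.09 to -0.27 and -1.99 to -0.60.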

How the results depend on the processing

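Chosen after seeing the data were the settings without chemoreceptor genes, with 1 probe set per gene, without both replicate 2 arrays, without the span trend and with the correlation fixed at its estimate; other settings were planned. The count of changed genes stayed between 555 and 759 with quantile normalization, median centring, either trend, no chemoreceptor genes, 1 probe set per gene or no span trend, and quantile normalization gave 473 higher genes. Testing all probe sets gave 419 changed probe sets, of which 375 list 1 gene. It was 1976 with array weights (592 higher, 1384 lower), 1255 without both replicate 2 arrays (952 lower) and 1 with each gene's own variance (1 higher, 0 lower), where few degrees of freedom remain per gene. All 584 changed genes were among the 1976, and 539 were among the 1255. Leaving out 1 array gave 143 to 520 genes, 89 to 193 higher and 54 to 337 lower, with fewer samples in each fit, and 2 to 5 lists.

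Replicate numbers did not pair the samples, since arrays of the same number had correlations of deviations from their group means of -0.46, -0.54 and -0.22, and no array correlated best with its own number. With the replicate block the count was 138 (76 higher, 62 lower), all among the 584, with fewer degrees of freedom. The block changed no list's call.

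Of the 24 genes with the largest rises and falls, all kept their call where tested, except under 4 settings; Stard6 was not tested with 1 probe set per gene. Each gene's own variance kept Fkbp9 alone, the trend lost Id2, and leaving out scrambled replicate 3 or anti-miR-30e replicate 3 lost Entpd6 and Prkar2a. The other 33 changed genes named by the rule held less well: 30 lost their call on leaving out at least 1 array (7 to 26 per array), with fewer samples in each fit, and Dicer1, Fzd1 and Tek kept it throughout. Chac1, Hmgcs1, Mmp3, Scd1 and Tnrc6b lost it whichever array was left out. Of the 33, the replicate block lost 28, among them Igf2, Pparg, Cyp51 and Ago2, each gene's own variance lost 33, and the remaining settings lost 0 to 3 each, Tarbp2 under 5 of them. Of the 61 named genes not past the threshold, 22 passed with array weights and 0 to 10 under any other setting. No named gene past the threshold changed sign. Those that did were not past it: with quantile normalization Alpl 0.0506 and Epor 0.0154; with median centring Alpl 0.0051; with no span trend Alpl 0.0078; with array weights Alpl 0.0803, Cd79b 0.0356, Ighm 0.0177 and Epor 0.0553; and without both replicate 2 arrays Alpl 0.0980, Tyrobp 0.0102, Cd79b 0.0663, Ighm 0.0446, Alas2 0.00954, Epor 0.117 and Robo4 0.0381. Leaving out 1 array gave -0.0843 to 0.0563 for Alpl, -0.105 to 0.0189 for Cd79b, -0.106 to 0.0551 for Epor and -0.0786 to 0.00155 for Ighm. The cause was not tested.

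Estimated correlation called 0 lists (cholesterol and small RNA machinery 0.904, smooth muscle 0.756 as adjusted p), and fry 0 (0.250, 0.211 and 0.211). The estimated correlation also leaves camera fewer degrees of freedom; with the correlation fixed at each list's estimate, which keeps those of the preset test, 0 lists were called (cholesterol 0.370, small RNA machinery 0.770, smooth muscle 0.128). Why fry called none was not tested. Genes with 1 probe set, which leave out Ago2 and Tarbp2, gave 0.0702 for small RNA machinery. Without both replicate 2 arrays smooth muscle was at 0.0656 and endothelial markers at 0.0402. Lists not called turned direction, the cause not tested, as follows, with adjusted p: quantile normalization, autophagy 0.870; array weights, miR-30 targets, BMP and TGF-beta, macrophage and interferon lists 0.898, chondrocyte, neutrophil and cell cycle 0.873, lymphoid 0.834 and autophagy 0.689; fry, adipocyte 0.703, interferon 0.930 and autophagy 0.835; 1 probe set, unfolded protein 0.845; no span trend, interferon 0.972; without both replicate 2 arrays, miR-30 targets, chondrocyte, BMP, neutrophil and lymphoid 0.572, macrophage 0.644, erythroid 0.855, cell cycle 0.0946, p53 0.946, autophagy 0.251 and hypoxia 0.853. Leaving out 1 array gave 5.38e-11 to 8.72e-06 for cholesterol synthesis, 4.05e-05 to 0.0296 for small RNA machinery, 0.00383 to 0.0526 for smooth muscle, 0.00764 to 0.772 for cell cycle, 0.0249 to 0.560 for MSC and stromal, 0.0396 to 0.273 for Wnt, 0.296 to 0.993 for miR-30 targets, 0.0662 to 0.992 for interferon, 0.650 to 0.992 for unfolded protein, 0.434 to 0.831 for autophagy, 0.507 to 0.992 for chondrocyte, 0.325 to 0.992 for neutrophil, 0.325 to 0.992 for lymphoid and 0.0612 to 0.968 for endothelial lists. In these fits the interferon, unfolded protein, cell cycle, autophagy, miR-30 targets, chondrocyte, neutrophil, lymphoid and endothelial lists turned direction without at least 1 array, none of them called where it turned, and the cause was not tested. The dim-gene filters, the highest-mean probe set, pseudocounts and the seed-site alternatives were not run. Signal over background was not at hand.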

Other observations

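The gene families, the ribosomal protein set and the tests of members varying together were chosen after the results were seen, as were the camera test with the correlation fixed at its estimate, the rule that this test and the one with the estimated correlation must agree, and the settings that remove the span trend and both replicate 2 arrays. Of 237 families sharing a symbol stem, 9 were called by camera with the preset correlation, and all had an adjusted p of 0.991 with an estimated correlation. The other splits of the 6 arrays called between 2 and 79 families. The Hoxa genes, which set position along the body axis, had negative values for 10 of 10 members, with Hoxa9 falling by 0.40 ± 0.07 and Hoxa7 falling by 0.35 ± 0.06 (SE). Their median was -0.18, with 1 positive member under quantile normalization and 1 without both replicate 2 arrays. Of 12 annexin genes, 9 were positive, and Anxa7 (0.49 ± 0.06) and Anxa8 (0.51 ± 0.10) rose. Of 18 Kdm genes, mostly histone demethylases, 16 were negative and Kdm5b fell by 0.35 ± 0.06. Of 1027 olfactory receptor genes 841 were negative and 2 fell, and their mean on scrambled replicate 2 was 0.10, against -0.05 to 0.0043 on the other arrays. Of the 1027, 186 were positive as given, 367 with quantile normalization and 463 without both replicate 2 arrays, where their median went from -0.05 to -0.007. The median over all genes as given was also below 0, at -0.025.

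The split of the arrays by oligo gave 584 changed genes and the highest of the other 9 splits gave 0, so 1 of 10 splits gave as many. For the gene lists, 8 of the 10 splits called as many as the 3 of the real one, and the highest of the others called 6. With 10 splits neither share can fall under 0.05. Each other split sets 2 arrays of 1 oligo and 1 of the other against the reverse, so it keeps part of any oligo difference. Mixing the oligos also widens the spread within its groups. The counts of the other splits therefore do not show what arrays without an oligo difference would give. Interferon, cell cycle and cholesterol synthesis lists were called in 6, 7 and 6 of the 9 other splits, and small RNA machinery and smooth muscle lists in 2 and 1. The interferon and cell cycle lists were not called between the oligos (camera, adjusted p = 0.860 and 0.342). On scrambled replicates 1 to 3 the interferon list means were -0.17, 0.03 and 0.21, and the cell cycle means 0.11, -0.18 and 0.02. Variation between arrays of 1 oligo can thus give calls at the preset correlation, so such a call alone does not show an oligo difference. Before adjustment, small RNA machinery had a p under 0.05 in 4 of the 9.

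Cholesterol synthesis genes exceeded other genes by a median of 0.22 ± 0.05 on the log2 scale (bootstrap SE over members). Here and below, such an SE takes members as independent, though these varied together (estimated correlation 0.737), and leaves out the spread between arrays. The trend with genomic span was small, with median differences of -0.038 for the 3984 genes of shortest span and -0.018 for the 3984 of longest. Removing it could therefore change little and left an excess of 0.22, which argues against that trend as the whole cause. Camera with the estimated correlation, which also has fewer degrees of freedom, gave p = 0.117, and with the correlation alone raised to that estimate p = 0.0462, so shared variation of members between arrays stays open. Without both replicate 2 arrays the excess was 0.12 ± 0.05, too near the midpoint between its former size and 0 to decide on these arrays of wide spread. An effect of the anti-miR-30e oligo on this pathway stays open as a hypothesis.

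Small RNA machinery genes lay below other genes by a median of -0.09 ± 0.05. Without both replicate 2 arrays it was -0.18 ± 0.05, which argues against those arrays as its cause. With the span trend removed it was -0.0917, past the midpoint between its former size and 0 by 0.05 ± 0.03 (SE paired over members), which argues against that trend as the whole cause. The estimated correlation gave p = 0.238, and the correlation alone raised to that estimate p = 0.166, so shared variation between arrays may account for the shift of the list. The limma test of a single gene does not depend on the correlation between members. Dicer1 and Ago2 passed it (adjusted p = 0.00287 and 0.00728), and Dicer1 kept its call whichever array was left out. Ago2 lost its call without anti-miR-30e replicate 3 and with the replicate block, and both lost theirs with each gene's own variance. Both were measured on the same arrays, so their falls are not independent of each other. A lower level of these genes in cells given an oligo against a microRNA is a hypothesis that these tests leave open.

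Ribosomal protein genes were the third pattern, with 49 of 54 positive, 3 rising (Rpl24 0.38 ± 0.07, Rpl5 0.29 ± 0.06 and Rpl7 0.27 ± 0.06) and a median excess of 0.15 ± 0.03. Their median stayed positive with quantile normalization (0.15), median centring (0.14) and without both replicate 2 arrays (0.09). The excess was 0.15 with the span trend removed and 0.10 ± 0.01 without both replicate 2 arrays, which argues against either as the whole cause. With the estimated correlation the camera p was 0.0646, and with the correlation alone raised to that estimate 0.0114, so shared variation between arrays stays open. At the preset correlation 7 of the 9 other splits gave a camera p under 0.05. Those splits keep part of any oligo difference, so they do not settle this. For all 3 patterns, the margin of 1 SE, and its pairing over the same members, were set after the values were seen: with no margin, cholesterol synthesis without both replicate 2 arrays would have counted against those arrays, and an unpaired one had left the span trend open for small RNA machinery. That SE covers the spread between genes alone, so decisions made with it do not allow for variation between arrays.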
